A study of Mus musculus with 12 samples.

How the data were processed

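Messenger RNA was measured in 12 libraries of primary mouse stromal vascular cells in 4 groups of 3, WT, TKO, CTL and Dox. Per the labels, TKO cells lacked miR-26a-1, miR-26a-2 and miR-26b, and WT and TKO cells were grown to confluency. Dox cells carried M2rtTA and an inducible eGFP.miR-26a transgene and received doxycycline at 1 mg/ml for 4 days (a dose high for cultured cells, printed as the labels give it), and CTL cells carried the same transgenes without treatment. The mice were 6 weeks old. Libraries were made from total RNA with a stranded kit that selects messenger RNA, and 75-base single reads were sequenced.

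Per the submitters' processing notes, reads were aligned with TopHat2 2.0.12 to GRCm38 (mm10), counted per gene with featureCounts 1.4.6 and tested with edgeR 3.8.6. StringTie 1.2.2 is also listed, without its role. The strand setting used in counting is not given in the sources, although the libraries were stranded. The signal values deposited by the authors were read counts scaled to a common library size and by 1 normalization factor per library. The log2 fold changes and log2 mean levels were made by the authors with edgeR and are printed only where the authors' deposited table is named. The score deposited by the authors is a likelihood ratio statistic and was not used here. Each p-value and false discovery rate in the deposited tables came from the authors' test. Judged from the deposited p-values, these rates were adjusted over about 54100 genes, more than were tested here. Adjusting over more genes raises these rates, but the authors' test also differs from limma, so the 2 are not directly comparable. For Fbxl19 in TKO against WT the authors' rate was 1.7e-05 and the limma adjusted p was 0.0025. The tables list 19262 genes for TKO against WT and 16785 for Dox against CTL, with no value of 0 in any of them, so only genes above 0 in all 6 libraries of a comparison are listed. The 2 tables list different genes and were normalized apart, so no fit over all 4 groups was run.

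Every low value was a whole multiple of 1 step per library, and dividing by that step gave the recovered reads. Between 95.1% and 100% of the values of a library were whole within 0.1 reads. The planned test took counts if the files held counts, and since they held scaled values, limma with a trend was applied to the log2 of the deposited signal. Count-based tests on the recovered reads were alternatives, and in TKO against WT they called 5769 genes by edgeR and 6354 by DESeq2 where limma called 5796. Depth sets the counting error only, and it ran from 19301969 to 83461601 recovered reads per library. All columns matched a sample, with 0 left over, by group and replicate number in the column names. The columns of Dox replicates 2 and 3 share the same sequencing-sample suffix, so the identity of these libraries, on which the pairing rests, comes from the replicate number alone. Of the gene identifiers 99.8% and 99.9% were found in the reference annotation, GENCODE vM21. For each gene 1 transcript gave the length, GC content and 3' UTR. Protein-coding transcripts came first, then those in the basic annotation set, then those with a complete end, and then the longest.

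Genes with a signal of at least 1 in at least 3 of the 6 libraries were tested, 12649 and 12634 of them. A pseudocount of 1 was added before the log2. R 4.3.3 was used with limma 3.58.1 (trend on mean level), edgeR 4.0.16 and DESeq2 1.42.0. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. SE is the standard error of the log2 fold change from limma. The lists, 31 with 462 genes, were written before the data were examined, as were the comparisons, the tests and the rule for the genes named. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a set move one way on balance.

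The genes named were Fbxl19 and the host genes, and the 10 highest and 10 lowest changes among genes past the threshold with a mean signal of at least 5 and no overlap between the groups. They also included up to 4 members with the smallest p in each list, reported targets past the threshold, and genes that moved in opposite directions in the 2 comparisons, 15 one way and 10 the other. Symbols that start with Gm and a digit, end in Rik, or end in -ps or -rs and a number were left out by that rule. A member of a list that did not pass is named with its values only. For Dox against CTL the rule was applied to the paired fit, a choice made after the data were seen. Ribosomal protein and nuclear respiratory-chain genes, and the overlap split by seed match, were also chosen after the data were seen.

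Pairing by replicate number was checked from the deviation of each library from its group mean. Across genes, same-numbered CTL and Dox libraries correlated at 0.863, 0.584 and 0.736 and the other combinations at -0.64 to -0.20. Same-numbered WT and TKO libraries correlated at 0.449, -0.135 and -0.293, so no pairing was assumed there. The paired fit had replicate number as a block, which had been set in advance as an alternative. The trend with transcript length and GC content was removed from each library with natural splines of 5 degrees of freedom.

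Seed matches were searched in the 3' UTR of 1 transcript per gene, as the 7-base match to the miR-26 seed and the 8-base match, which adds an A opposite the first base of the microRNA. Genes counted as without any match also lacked the weaker 7-base site that holds this A and a shorter seed match. The shift of genes with a match was tested by a 2-sided permutation test with 100000 resamples, against genes matched on 3' UTR length and mean level, and against 100 heptamers of the same bases. Overlaps and shares were tested by Fisher's exact test, adjusted over the tests of the same family. The share of 50-base stretches that a gene has in common with other genes was computed from the annotated transcripts.

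The procedure was tested on simulated data made from the recovered depth of each comparison, with known changes of log2 0.5, 1 and 2. Only genes with a mean signal of at least 5 were changed, 66 or 67 of each size. The shares recovered thus do not cover genes of lower signal, and far fewer genes were changed than were called in TKO against WT. In TKO against WT 34.8%, 95.5% and 100% of these were recovered, with 14 false among 168 calls. In Dox against CTL 4.5%, 76.1% and 98.5% were recovered, with 7 false among 127, and in the paired fit 78.8%, 100% and 100%, with 7 false among 193. An added trend in length and GC content gave 3572 false calls, and 16 once it was removed. That trend was the same in every TKO library, with a Spearman correlation with length of -0.74 against -0.32 in the real comparison. It thus does not show how well removal works on a trend of another shape. Alternatives included library-size scaling, median centring, pseudocounts of 0.1 and 5, no filter, a stricter filter with a mean of at least 10, thresholds of 0.01 and of at least 1 log2 unit, DESeq2, a replicate block, and leaving out each replicate. Removing the trend, edgeR, the replicate block together with trend removal, and the use of the blocked fit as a second leading fit for Dox against CTL were added after the data were seen.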

Results

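The series measured messenger RNA in 12 libraries of cultured mouse cells by RNA sequencing. The cells were the stromal vascular fraction of white adipose tissue from C57BL/6 mice, which holds the progenitors that can turn into fat cells, grown as primary culture. The first comparison set 3 wild-type libraries (WT) against 3 triple-knockout libraries (TKO) from cells lacking every miR-26 gene (miR-26a-1, miR-26a-2 and miR-26b). miR-26 is a microRNA, a short RNA that lowers the output of messenger RNAs whose 3' untranslated region (UTR) pairs with its seed. The second comparison set 3 untreated libraries (CTL) against 3 doxycycline-treated libraries (Dox) of cells carrying a transgene that makes miR-26a when doxycycline is present. The stated purpose was to find miR-26 targets in adipocyte progenitors, and the series title names Fbxl19 as such a target. The labels do not say whether the replicates of a group are separate animals or separate cultures, so p-values from limma, edgeR, DESeq2 and camera measure only the spread between these samples. The permutation and Fisher's exact tests below compare sets of genes, treat genes as independent and say nothing of the spread between libraries.

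The deposited values were a signal, read counts scaled to a common library size and by 1 factor per library. Whole read counts were recovered from them at a tolerance of 0.1. The recovered depth was 57941779, 61307004 and 54978095 reads in WT and 75739021, 71455211 and 83461601 in TKO. It was 24122542, 20182665 and 20835676 in CTL and 19301969, 25785424 and 24334606 in Dox. The 100 genes with the most reads took 23.9% to 28.4% of the reads in these libraries. After the filter on low values, 12649 genes were tested in TKO against WT and 12634 in Dox against CTL.

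The tables list no row for miR-26 itself, for eGFP or for the transactivator, so neither the loss nor the induction of miR-26 was measured directly. The miR-26 genes lie in introns of Ctdsp1, Ctdsp2 and Ctdspl, which encode small phosphatases that act on RNA polymerase II. Ctdsp1 read 79.9, 75.7 and 85.5 in WT and 65.1, 70.3 and 59.4 in TKO, a log2 fold change of -0.30 ± 0.08 (SE, n = 3 per group, limma adjusted p 0.024). Ctdspl read 40.5, 39.2 and 37.2 in WT and 28.2, 33.0 and 27.7 in TKO, a change of -0.39 ± 0.09 (limma adjusted p 0.011). Ctdsp2, which carries a miR-26 seed match of its own, went the other way, from 198, 192 and 228 in WT to 239, 301 and 268 in TKO, a change of 0.38 ± 0.11 (limma adjusted p 0.026). Scaling by library size ended the calls of Ctdsp1 (-0.18, adjusted p 0.162) and Ctdspl (-0.27, adjusted p 0.064), and with the length and GC trend removed Ctdsp1 was at -0.47 (adjusted p 0.0022). The Ctdsp2 call ended without WT replicate 1 (adjusted p 0.089), WT replicate 2 (0.098) or TKO replicate 3 (0.059), and the Ctdsp1 call without WT replicate 1 (0.071), WT replicate 3 (0.082) or TKO replicate 3 (0.056). Each host gene was still transcribed in every TKO library. With doxycycline Ctdsp2 read 198, 246 and 196 against 284, 313 and 291 in CTL, a change of -0.48 that passed only when replicates were paired by number (limma adjusted p 0.021, and 0.121 without replicate 1). Ctdsp1 and Ctdspl did not pass in either fit of Dox against CTL.

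Fbxl19, the gene in the series title, encodes an F-box protein, the part of a ubiquitin ligase that picks its substrates. It is listed as ENSMUSG00000030811.14 and lies on chromosome 7 at 127744543 to 127769483 on the + strand (GRCm38). Its signal was 19.4 ± 2.57 in WT and 32.4 ± 2.13 in TKO (SD, n = 3), and all 3 TKO libraries were above all 3 WT libraries. The log2 fold change was 0.72 ± 0.11 (SE, limma adjusted p 0.0025), and it was 0.53 once a trend with transcript length and GC content was removed (adjusted p 0.0015). With doxycycline the signal was 20.8 ± 1.30 against 26.9 ± 0.44 in CTL (SD, n = 3), again with no overlap between the groups. That change of -0.36 ± 0.09 did not pass (limma adjusted p 0.57), nor did it pass with replicates paired (0.079, and 0.537, 0.006 and 0.108 without replicate 1, 2 and 3). It passed in the paired fit with the trend removed (-0.39, adjusted p 0.019). The 3' UTR of Fbxl19 spans 1546 bases and holds a pair of sites with the sequence TACTTGAA, a full match to the miR-26 seed. They lie in exon 11 at 127768710 to 127768717 and at 127768739 to 127768746. In the authors' deposited table the change of Fbxl19 was 0.74 with a false discovery rate of 1.7e-05 for TKO, and -0.37 with a rate of 1 for Dox.

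**Figure D1:**
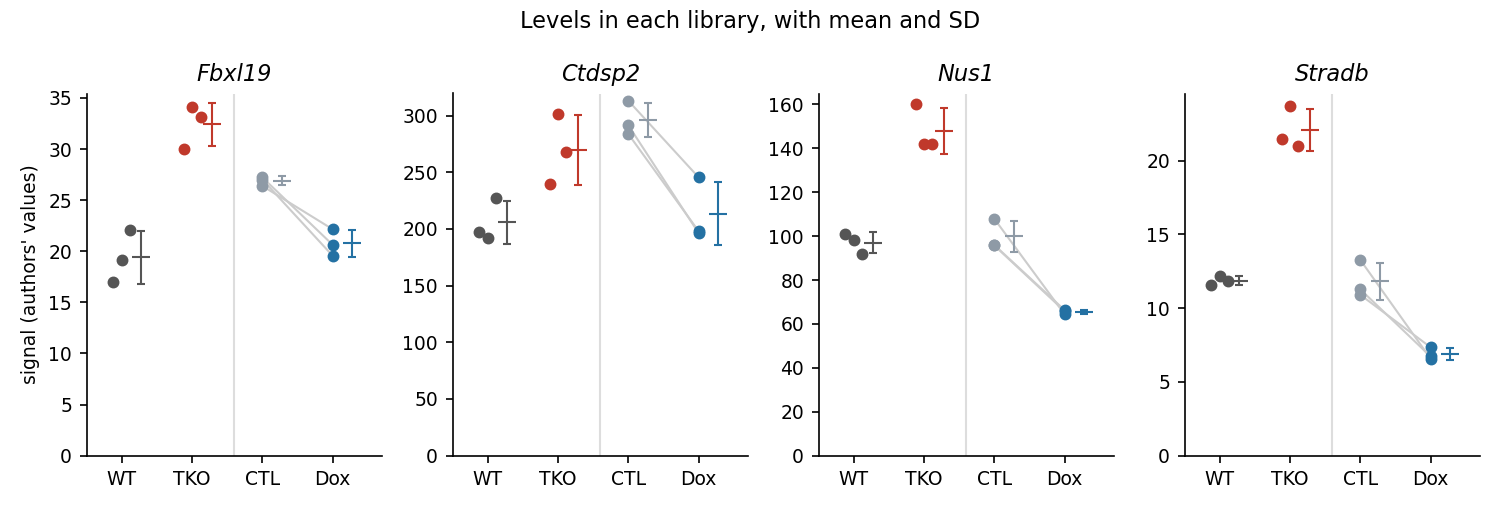
Signal in the authors' values (vertical axis) of Fbxl19, Ctdsp2, Nus1 and Stradb in each library of WT, TKO, CTL and Dox; points are libraries, lines the mean and SD of 3. Fbxl19 lies at 30.0 to 34.1 in TKO and at 16.9 to 22.1 in WT.

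TKO against WT asked which messenger RNAs change when miR-26 is absent. Cebpa, a transcription factor that drives fat-cell differentiation, rose from 11.95 ± 1.13 to 41.2 ± 18.0 (SD, n = 3), a log2 fold change of 1.63 ± 0.28 (SE). Ebf1, another factor of the adipocyte programme, fell from 181 ± 26.8 to 79.8 ± 24.7, a change of -1.21 ± 0.22. Tcf7l2, a Wnt-pathway factor that restrains adipogenesis, fell from 34.4 ± 2.53 to 19.2 ± 1.56, a change of -0.81 ± 0.09, and Nr2f2, a nuclear receptor with a like role, fell by 0.75 ± 0.10. Hmga2, a chromatin protein of proliferating progenitors and itself a reported miR-26 target, fell by 1.35 ± 0.29. Dgat1, an enzyme of the last step of triglyceride synthesis, read 9.53, 10.3 and 10.03 in WT and 20.9, 22.8 and 17.8 in TKO, a rise of 0.96 ± 0.10. All of these passed at a limma adjusted p between 8.1e-04 and 0.00995.

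Among the genes with the largest rise were Rpl39, a ribosomal protein gene, at 38.6, 35.8 and 45.8 in WT and 292, 346 and 287 in TKO (2.92 ± 0.12, limma adjusted p 1.0e-04), and S100a6, a calcium-binding protein gene, at 276, 263 and 278 in WT and 1261, 1358 and 1112 in TKO (2.18 ± 0.09, adjusted p 1.0e-04). Tspo, which encodes a protein of the outer mitochondrial membrane, rose by 2.57 ± 0.21, Atp5e, a subunit of the ATP synthase, by 2.53 ± 0.10, and Ndufa2, a subunit of respiratory complex I, by 2.23 ± 0.09. The respiratory-chain gene mt-Nd5, read from mitochondrial DNA, fell from 10903 ± 910 to 2558 ± 288 (SD, n = 3), a change of -2.09 ± 0.13 (limma adjusted p 2.5e-04). Egr1, an immediate-early transcription factor, fell by 1.67 ± 0.23, and Hcfc1r1, which encodes a regulator of the transcription cofactor Hcfc1, fell by 1.65 ± 0.07. Rps10, Rpl22l1, Sec61b, Srp54b, 9930111J21Rik2 and mt-Co1 were also among the most changed, but from 0.41 to 0.94 of their 50-base stretches occur in other genes, so their changes are uncertain. In groups picked after the values were seen, 57 of 77 ribosomal protein genes rose and 9 fell (median 0.77). With the trend removed 50 rose and 14 fell (median 0.49). The changes of these 77 genes ran from -0.97 to 2.92 (SD 0.77), and genes with shared 50-base stretches were not left out. Of 71 nuclear respiratory-chain genes 52 rose and 2 fell (median 0.61), and with the trend removed 40 rose and 13 fell (median 0.39).

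Gene lists were fixed in advance, and 29 of the 31 held enough genes for a test in TKO against WT. Of all 12649 genes tested 45.8% passed, 2930 higher and 2866 lower. Counts of members near or below that share are no sign that a list responded. Of the 12 mitochondrially encoded genes 0 rose and 11 fell (0 and 11 adjusted over the list alone; median -1.47), led by mt-Nd5, mt-Nd2 (-1.89) and mt-Nd1 (-1.88), and mt-Co3 did not pass. It was the only list past camera (adjusted p 2.8e-06), and with an estimated correlation its adjusted p was 0.49. Among 10 inhibitors of adipogenesis 4 fell, 0 rose and 6 did not pass (3 and 0 adjusted over the list alone), with Zfp521, a zinc-finger repressor of the fat-cell fate, at -0.80 beside Tcf7l2 and Nr2f2. Among 19 positional identity genes 7 fell, 0 rose and 12 did not pass (12 and 0 adjusted over the list alone), among them Tbx5 (-1.14), Shox2 (-1.01), Hoxc6 (-0.74) and Hoxa7 (-0.65), which mark the body region a mesenchymal cell comes from. Both lists missed the camera threshold (adjusted p 0.055 and 0.051) and passed it with the length and GC trend removed (0.012 each), where the adjusted p with an estimated correlation was 0.94 and 0.46. With the trend removed 6 of the inhibitors and 11 of the positional identity genes fell, and 0 rose in each list.

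Of 17 adipogenic transcription factors 2 rose, Cebpa and the sterol regulator Srebf1 (0.71), and 4 fell, with the zinc-finger factor Egr2 (-0.85) beside Ebf1 (2 and 4 adjusted over the list alone); the list's median, -0.06, became 0.05 with library-size scaling. Pparg, the master regulator of adipogenesis, did not change measurably (-0.09, limma adjusted p 0.71). Of 21 adipocyte lipid genes 3 rose and 18 did not pass (1 adjusted over the list alone, none down), and 5 rose with the trend removed. The triglyceride enzyme Dgat2 (1.19, limma adjusted p 0.015) lost its call without WT replicate 1 (0.056) or WT replicate 2 (0.055), and the adrenergic receptor Adrb3 (adjusted p 0.028) lost it without WT replicate 1, 2 or 3 (0.092, 0.070 and 0.066) and without TKO replicate 1 or 2 (0.072 and 0.060). The hormone gene Adipoq read 1.18, 1.85 and 2.80 in WT and 15.97, 16.26 and 0.787 in TKO (adjusted p 0.20), and the fatty-acid carrier Fabp4 25.49, 25.997 and 25.57 in WT and 83.5, 80.7 and 27.1 in TKO (adjusted p 0.063). Of 5 thermogenic genes 3 fell and 0 rose (1 fell with the trend removed), led by the coactivator Ppargc1a (-0.68), whose call ended with the trend removed (adjusted p 0.11). Of 15 adipocyte progenitor markers 2 rose, the adhesion molecule Icam1 (1.11) and the ectonucleotidase Nt5e (0.73), and 4 fell, among them the surface protein Thy1 (-0.86), with the same counts adjusted over the list alone.

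Of 27 reported miR-26 targets only Fbxl19 rose, 8 fell and 18 did not pass (1 and 7 adjusted over the list alone; median -0.24, camera adjusted p 0.25). With the length and GC trend removed 2 rose, 7 fell and the median was -0.04. Those that fell include Hmga2, the kinase adaptor Tab3 (-0.71), the cyclin Ccne2 (-0.64) and the DNA demethylase Tet2 (-0.52). Fbxl19 is on that list and in the series title, so it is not independent evidence. The shedding protease Adam17 did not pass (0.14, limma adjusted p 0.14) but did with the trend removed (0.27, adjusted p 0.0097). Among 9 partners of the Fbxl19 ubiquitin ligase 2 rose, Fbxl19 and the ring protein Rbx1 (0.75), and 2 fell, one of them the related F-box gene Kdm2a (-0.78), with the same counts adjusted over the list alone; the list's median went from -0.04 to 0.07 with library-size scaling.

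Several other lists held members that rose and members that fell. Among 13 immediate-early genes 4 fell, Egr1, the RNA decay factor Zfp36 (-1.23), the zinc-finger factor Klf6 (-0.92) and the phosphatase Dusp1 (-0.66), and 2 rose, with the same counts adjusted over the list alone (6 and 1 with the trend removed). Among 20 G2/M and mitosis genes 3 rose, with Cdc20 (0.99), an activator of the anaphase complex, and the mitotic kinase Cdk1 (0.52), and 6 fell, with the proliferation marker Mki67 (-1.08) and the spindle factor Tpx2 (-0.63), again with unchanged counts adjusted over the list alone. Of 12 hypoxia and glycolysis genes 4 rose, led by the lactate dehydrogenase Ldha (1.06), and the growth factor Vegfa fell (-0.34; 3 and 1 adjusted over the list alone). The glycolytic enzyme Eno1 (0.92) is uncertain, since 0.72 of its 50-base stretches occur in other genes. Of 20 cholesterol synthesis genes 8 fell, among them Cyp51 (-0.43) and Nsdhl (-0.41), which act on sterol intermediates, and 2 rose (8 and 2 adjusted over the list alone). Of 19 ATF4 stress response genes 6 rose, led by the mTOR inhibitor Ddit4 (1.47), and 2 fell, among them the amino-acid transporter subunit Slc3a2 (-0.31), whose call ended with library-size scaling (adjusted p 0.068). With the trend removed 3 of the ATF4 genes rose and 5 fell. The median of the cholesterol synthesis list changed sign with library-size scaling (-0.03 to 0.10), and that of the ATF4 list with median centring (0.01 to -0.04).

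Of 27 collagen and matrix genes 3 rose and 1 fell (2 and 0 adjusted over the list alone), with Col3a1, a fibrillar collagen, at 0.79 (limma adjusted p 0.0031, and 0.143 with no filter on low values). Of 12 contractile genes the actin-binding Tagln rose (0.82) and 4 fell, led by the smooth-muscle gene Smtn (-0.69). Of 15 inflammatory genes 3 rose and 0 fell (2 and 0 adjusted over the list alone), among them Icam1 and the NF-kappaB subunit Relb (0.78). Of 15 interferon response genes 2 rose and 3 fell (1 and 3 adjusted over the list alone), with the RNA sensor Ddx58 (-0.58) and the signal transducer Stat2 (-0.56) lower. Of 13 p53 targets 4 rose and 1 fell (4 and 1 adjusted over the list alone), but the cell-death gene Bax (0.75) lost its call with the trend removed (adjusted p 0.107). Of 16 TGF-beta response genes 2 rose and 1 fell (1 and 1 adjusted over the list alone), with the matricellular gene Cyr61 at -0.55. Of 9 endothelial markers 1 rose and 1, the receptor Flt1 (-0.64), fell. Of 21 G1/S and replication genes 1 rose and 2 fell, Ccne2 among them (0 and 1 adjusted over the list alone). The median of the TGF-beta list changed sign with library-size scaling (-0.11 to 0.01), and that of the G1/S list with median centring (0.05 to -0.01). Of 8 Wnt target genes 1 rose, the Wnt deacylase Notum (0.87, limma adjusted p 0.016, and 0.077 with the trend removed), and 0 fell. Of the 14 macrophage, 6 mesothelial, 6 epithelial, 6 Schwann cell and 5 skeletal muscle markers tested with limma 0 passed. Of the macrophage markers 13 of 14 had a fold change above 0 (median 0.59), and of the epithelial markers 0 of 6 (median -0.45). TKO replicate 2 stood apart in the macrophage lysozyme Lyz2, at 181 against 34.1 and 30.5 in the other TKO libraries, and in the inflammatory gene Saa3, at 155 against 6.56 and 11.6. In these lists and in the contractile, thermogenic and endothelial lists the counts were the same adjusted over the list alone.

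The limma test called 5796 of 12649 genes, 45.8%, at an adjusted p under 0.05, with 2930 higher and 2866 lower in TKO. At the unadjusted p under 0.05 there were 6835 genes, and in 58.8% of genes the groups did not overlap, against 10% by chance. edgeR called 5769 genes and DESeq2 6354 from the recovered reads, and 498 of the called genes changed by at least 1 log2 unit. The authors' deposited table holds 4775 genes at a false discovery rate under 0.05, 2625 higher and 2150 lower, with rates adjusted over about 54100 genes. Library-size scaling shifted the median gene by 0.11, so that 66.7% of called genes were higher in place of 50.6%. The change also depended on the transcript, with a Spearman correlation across genes of -0.32 with transcript length and 0.31 with GC content, and these explained 15.8% of the variance. The median change was 0.39 over the 318 genes with transcripts under 750 bases and -0.19 over the 2712 at or above 5000 bases. In Dox against CTL length and GC content explained 2.0%.

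**Figure D2:**
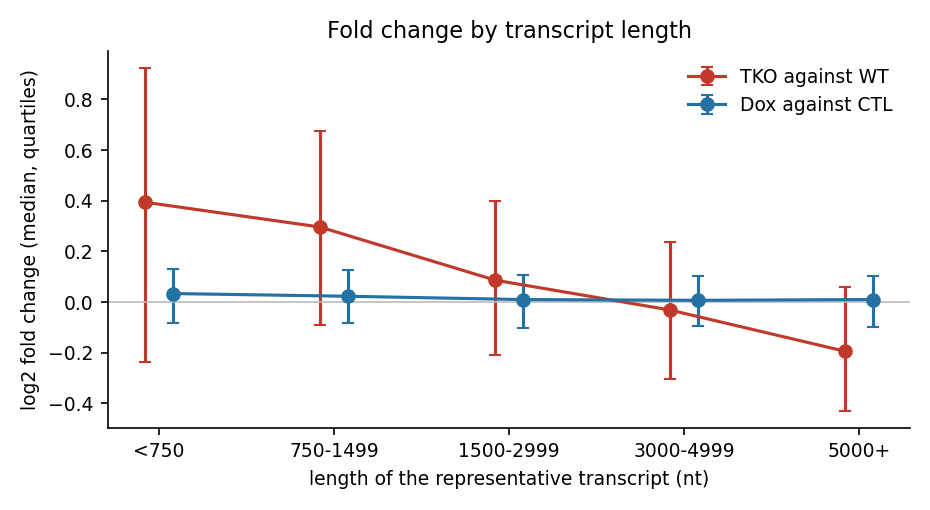
Median log2 fold change (vertical axis) of genes binned by transcript length in bases (horizontal axis) in TKO against WT and in Dox against CTL; bars span the quartiles of genes. The TKO medians run from 0.39 under 750 bases to -0.19 at or above 5000 bases.

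Dox against CTL asked which messenger RNAs change when miR-26a is made in excess. Lipa, the lysosomal enzyme that frees fatty acids from stored esters, read 121, 113 and 115 in CTL and 61.9, 62.9 and 49.6 in Dox, a log2 fold change of -0.997 ± 0.087 (SE of the paired fit, n = 3 pairs, limma adjusted p 0.0036). Zdhhc20, an enzyme that attaches palmitate to proteins, fell by 0.89 ± 0.08, and Adam17, a protease that sheds cytokines and receptors, fell by 0.76 ± 0.07 (adjusted p 0.0036 each). Angptl4, a secreted inhibitor of lipoprotein lipase, was higher, at 45.7 ± 10.3 against 25.2 ± 3.81 (SD, n = 3), a change of 0.82 ± 0.13 (limma adjusted p 0.021). These adjusted p-values come from the fit that pairs CTL and Dox libraries by replicate number. The unpaired limma test, which was the choice made before the data were examined, called 0 genes. Among other genes lower in the paired fit, Siae (-0.85) and Glb1 (-0.84) encode lysosomal hydrolases, Apod (-0.99) a lipid carrier, Rgs4 (-1.13) a brake on G-protein signalling and Bivm (-0.86) a protein of little-known role. Lpl, which encodes lipoprotein lipase, fell by 0.48 (adjusted p 0.024). Among those higher were Fbn2 (0.77), a microfibril protein, and Plxna4 (0.67), a semaphorin receptor.

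In the paired fit 10 lists passed camera, none of them with an estimated correlation (adjusted p 0.70 each). Of 20 interferon response genes 3 fell, Oasl2 (-0.78), which encodes an oligoadenylate synthetase-like protein, the ubiquitin-like modifier Isg15 (-0.76) and the receptor transporter Rtp4 (-0.75), and 0 rose (14 and 0 adjusted over the list alone; camera adjusted p 2.1e-09). Without replicate 1 the calls of Isg15 (adjusted p 0.053) and Rtp4 (0.115) ended. Of 27 reported miR-26 targets 4 fell and 0 rose, Adam17 among them (9 and 2 adjusted over the list alone; camera adjusted p 1.0e-04). Of 12 mitochondrially encoded genes 2 fell, the ribosomal RNA genes mt-Rnr1 (-0.83) and mt-Rnr2 (-0.68), and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p 0.013). With the trend removed 3 of them fell and 2 rose, the respiratory complex I genes mt-Nd2 (0.50) and mt-Nd4 (0.30, uncertain because 0.62 of its 50-base stretches occur in other genes), and the camera call ended (adjusted p 0.090). Of 15 inflammatory genes 1 fell, the chemokine Cxcl5 (-1.38), and 0 rose (4 and 1 adjusted over the list alone; camera adjusted p 0.0085). Of 19 ATF4 stress response genes 1 rose, the mitochondrial folate enzyme Mthfd2 (0.35, limma adjusted p 0.046, and 0.202 and 0.059 without replicate 1 and 3), and 1 fell, the cystine transporter Slc7a11 (-0.60, and adjusted p 0.138 without replicate 1), with 8 and 1 adjusted over the list alone and a camera adjusted p of 0.0037. With the trend removed 6 of the ATF4 genes rose and 1 fell, 8 interferon genes fell and 0 rose, and 7 reported targets fell and 1 rose. Of the 3 host genes 1 fell, Ctdsp2, over all genes and adjusted over the list alone (camera adjusted p 0.026).

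The remaining lists past camera had medians above 0 and 0 genes past the test over all genes in each, and none passed fry (adjusted p 0.33 to 0.52). They were TGF-beta response (16 genes, median 0.13, 2 higher adjusted over the list alone, camera adjusted p 0.013), hypoxia and glycolysis (12 genes, median 0.11, 0 adjusted over the list alone, camera adjusted p 0.014), G1/S and replication (21 genes, median 0.13, 4 higher adjusted over the list alone, camera adjusted p 0.015) and epithelial markers (6 genes, median 0.26, 1 higher adjusted over the list alone, camera adjusted p 0.017, and 0.123 with the trend removed). In the unpaired fit 4 lists passed camera, and with an estimated correlation none did: interferon response (median -0.52, camera adjusted p 4.5e-07, estimated 0.94), reported miR-26 targets (median -0.14, camera adjusted p 5.6e-04, estimated 0.52), host genes (median -0.17, camera adjusted p 0.0496, estimated 0.94) and mitochondrially encoded genes (median -0.18, camera adjusted p 0.0496, estimated 0.94). Adjusted over the list alone, 1 interferon gene, 3 reported targets, 1 host gene and 2 mitochondrial genes were lower there. An effect in Dox and not in TKO, or the reverse, is not shown to differ, since the difference was not tested.

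The unpaired limma test called 0 genes (smallest adjusted p 0.265), with 748 at an unadjusted p under 0.05, 309 higher and 439 lower. edgeR called 0 genes and DESeq2 99, 10 higher and 89 lower. In 12.2% of genes the groups did not overlap. The share by chance, 10%, is for libraries that are not paired. Same-numbered CTL and Dox libraries were alike, so the shares cannot be compared directly. The fit paired by number, an alternative set in advance, called 265 genes, 71 higher and 194 lower. It was taken as a second leading fit only after the data were seen, because same-numbered CTL and Dox libraries were alike. Without replicate 1, 2 and 3 the paired fit called 134, 1534 and 591 genes. The authors' deposited table holds 10 genes at a false discovery rate under 0.05, all lower, among them Lipa (-1.0025), Zdhhc20 (-0.91), Adam17 (-0.77) and Nus1 (-0.61). Because no treated culture without the transgene is among the samples, doxycycline treatment and miR-26a induction are not separated in this comparison.

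Messenger RNAs with a miR-26 seed match in the 3' UTR were lower with doxycycline as a group. Among 11884 genes searched, 1366 held a match of at least 7 bases, and their median log2 fold change differed from that of the other genes by -0.08 (2-sided permutation test, p 1e-05, the smallest that 100000 resamples can give). Without Dox replicate 2 the difference was -0.053. Genes with the full 8-base match had a median of -0.13, with quartiles at -0.29 and 0.01, and 73.0% of the 599 genes were below 0. Genes with only the 7-base match had a median of -0.03 (767 genes, 58.3% below 0), and the 9306 genes with no match a median of 0.02. Of the 191 genes searched that were lower in the paired fit, 89 held a match, 46.6% against 11.5% of all searched genes (odds ratio 7.12, Fisher's exact test, adjusted p 1.2e-33). Of 69 higher genes 2 held one (odds ratio 0.23, adjusted p 0.025). In TKO against WT the difference was -0.13 (permutation p 1e-05, the smallest possible), the direction of lower signal in cells without miR-26, and it was -0.081 without TKO replicate 2. It became 0.04 (p 0.0098) with the length and GC trend removed, and was -0.03 (p 0.159) against genes matched on 3' UTR length and level. Genes with a match made up 7.5% of those higher in TKO (odds ratio 0.55) and 14.03% of those lower (odds ratio 1.34), against 11.6% of all. With the trend removed the shares were 12.5% of the higher genes (Fisher's exact test, adjusted p 0.096) and 9.1% of the lower genes (odds ratio 0.72, adjusted p 7.0e-06).

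**Figure D3:**
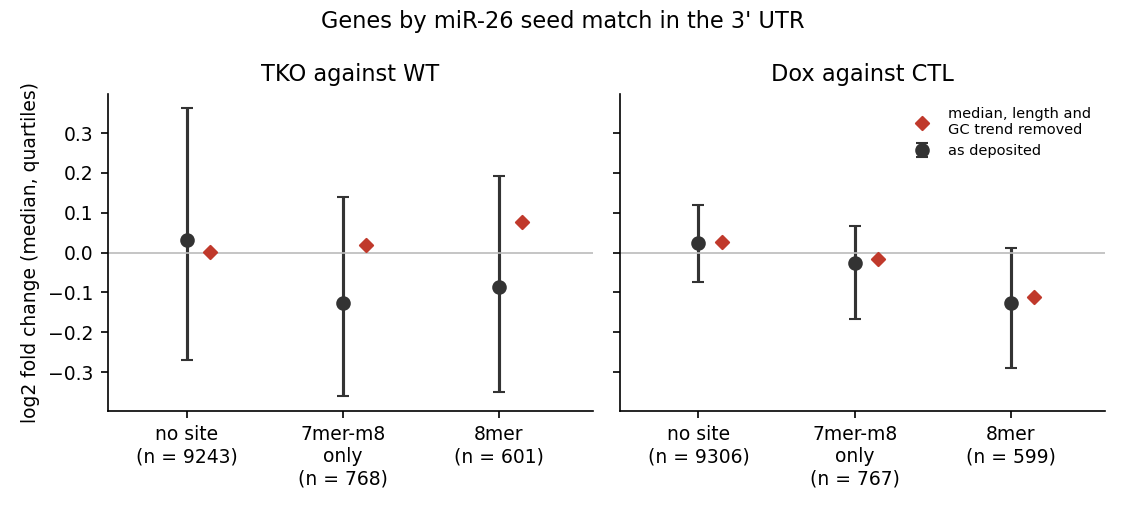
Median log2 fold change (vertical axis) of genes grouped by the miR-26 seed match in their 3' UTR (horizontal axis) in each comparison; bars span the quartiles of genes and red diamonds give medians with the length and GC trend removed. In Dox against CTL the median is -0.13 for the 8-base match and 0.02 for no match.

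The calls of both comparisons were set side by side to find genes higher without miR-26 and lower with its excess. Nus1, a subunit of the enzyme that makes dolichol, read 101.1, 98.1 and 91.9 in WT, 160, 142 and 142 in TKO, 95.8, 96.0 and 108 in CTL, and 65.8, 66.3 and 64.4 in Dox. Its log2 fold changes were 0.60 ± 0.07 and -0.60 ± 0.08 (limma adjusted p 0.0013, and 0.012 paired). Stradb, a pseudokinase that activates the kinase Lkb1, moved by 0.84 and -0.70, Snn, a small membrane protein, by 0.65 and -0.65, Ttpal, a lipid-transfer protein, by 0.59 and -0.58, and Tmem173, the adaptor of cytosolic DNA sensing, by 0.59 and -0.79. Nus1, Stradb, Snn and Ttpal held the 8-base seed match in the 3' UTR searched, and Tmem173 held no match. The cadherin gene Cdh3 moved the other way, by -0.90 in TKO and 0.95 with doxycycline (paired adjusted p 0.0036). Of 12373 genes tested in both comparisons, 46 were higher in TKO and lower in the paired Dox fit, where 45.2 would overlap by chance (odds ratio 1.02, Fisher's exact test, adjusted p 0.86), and leaving out 1 replicate pair moved the count between 30 and 216. The opposite overlap held 13 genes (15.9 by chance, adjusted p 0.634), from 8 to 145 with 1 pair left out. Genes higher in both numbered 7 (16.3 by chance, adjusted p 0.026; 76 against 84.8 with the trend removed, adjusted p 0.38; 97 against 83.3 at the unadjusted p of the unpaired fit, adjusted p 0.21) and genes lower in both 33 (44.1 by chance, adjusted p 0.115). With the unpaired Dox fit every overlap was 0. A split by seed match was chosen after the data were seen. Among 1355 genes with a match 27 were higher in TKO and lower with doxycycline, where 13.6 would be by chance (odds ratio 2.63, adjusted p 0.0029). Among 10330 searched genes without a match there were 19, against 25.3 by chance (adjusted p 0.33). With the trend removed there were 65 with a match against 50.3 by chance (adjusted p 0.053) and 57 without against 77.0 (adjusted p 0.044). Across the genes tested in both, the fold changes had a Pearson correlation of -0.005 and a Spearman correlation of 0.02. The Pearson value ran from -0.11 without Dox replicate 2 to 0.086 without Dox replicate 3, and genes are not independent replicates.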

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

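The tests with the length and GC trend removed, with edgeR, with block and trend removal together, the alternatives of the paired fit, and the leave-one-out runs of the seed-match shift were chosen after the data were seen. Where no cause is given below, the cause was not tested. The 5796 genes called in TKO against WT became 3518 at an adjusted p of 0.01 and 498 at an absolute log2 fold change of at least 1, stricter by construction, and stayed within 1.5 times under the 11 other settings (3938 to 5723 with 1 replicate left out). The Fbxl19 change in TKO passed under all 11 settings and ran from 0.63 to 0.81 with 1 replicate left out. The 1 list past camera in TKO became 0 with an estimated correlation and 3 each with fry, with library size only, with no filter, with the trend removed, with a replicate block, and with block and trend removal together (1 to 3 with 1 replicate left out).

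For Dox against CTL, 0 genes became 99 with DESeq2, 265 with a replicate block and 925 with block and trend removal. The 4 lists there became 0 with an estimated correlation and with fry, 2 each with library size only, no filter and the stricter filter, 10 with a replicate block and 8 with block and trend removal (5 to 9 with 1 replicate left out). In the paired fit, 265 genes became 87 with no filter, 403 with DESeq2, 925 with the trend removed, 7 at an adjusted p of 0.01 and 11 at an absolute log2 fold change of at least 1 (134 to 1534 with 1 replicate left out). Its 10 lists became 0 with an estimated correlation and with fry. The Fbxl19 change of -0.36 passed at -0.39 with block and trend removal together, which is the same fit as the paired fit with the trend removed. In the paired fit it ran from -0.42 to -0.31 with 1 replicate left out, and it passed without replicate 2 (-0.42, limma adjusted p 0.006).

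The overlap of genes higher in TKO and lower with doxycycline, 0 unpaired, became 121 at an unadjusted p of 0.05, 26 with DESeq2 and 51 with a replicate block in both fits. Its 46 with the Dox replicates paired became 1 at an adjusted p of 0.01, 1 at a fold change of at least 1, 258 at an unadjusted p of 0.05, 71 with DESeq2, 17 with no filter and 122 with the trend removed (30 to 216 with 1 replicate left out). The opposite overlap, 0 unpaired, became 70, 3 and 13 under the unadjusted p, DESeq2 and a replicate block. Its 13 with the Dox replicates paired became 1 at an adjusted p of 0.01, 0 at a fold change of at least 1, 247 at an unadjusted p of 0.05, 24 with DESeq2, 2 with no filter, 8 with the stricter filter and 72 with the trend removed (8 to 145 with 1 replicate left out). The correlation of fold changes across genes ran from -0.11 to 0.086 with 1 replicate left out. The seed-match shift in TKO, -0.13, was -0.0292 against matched genes (no longer past the test), and reversed to 0.0364 with the trend removed and to 0.0176 against permuted heptamers (-0.163 to -0.081 with 1 replicate left out). The shift with doxycycline kept its direction and stayed past the test under the 5 settings that gave a test (-0.115 to -0.053 with 1 replicate left out).

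Among single genes, 1291 results in TKO against WT were the same under other settings and 70 lost their call, and 661 and 89 with 1 replicate left out. In Dox against CTL 465 were the same and 129 gained a call, and in the paired fit 417 were the same and 67 lost it (144 the same, 19 lost, 1 gained and 1 reversed with 1 replicate left out). Ctdspl in Dox against CTL, -0.06, ran from -0.173 to 0.0274 with 1 replicate left out, reversing without Dox replicate 3, and reversed to 0.0149 in the paired fit without replicate 3. WT and TKO replicate numbers do not pair, so a replicate block there has no basis in the samples. A fit of all 4 groups together was not run, since the tables list different genes and were normalized apart. Depth limits genes near a signal of 1, which are filtered, and the lower depth of CTL and Dox leaves larger counting error there.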

Other observations

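The bound that decides the test against genes matched on 3' UTR length and level (a test set in advance as an alternative), the seed-match shift with the length and GC trend removed, and the count of lowered genes without a seed match, were chosen only after the results they measure were seen. Genes of other cell types differed between libraries of the same group. Lyz2, an abundant lysozyme of macrophages, read 24.1, 18.0 and 31.0 in WT and 34.1, 181 and 30.5 in TKO, and the macrophage receptor Csf1r and complement gene C1qa were also highest in TKO replicate 2, at 26.7 and 16.03. Saa3, an acute-phase gene, read 155 there, against 6.56 and 11.6 in the other TKO libraries. Adipocyte genes were high in TKO replicates 1 and 2 and not in replicate 3, with Plin1, which coats lipid droplets, at 14.5, 13.9 and 0.986 and Cfd, the adipsin gene, at 12.6, 19.3 and 0.388. In the transgenic cultures the epithelial keratin Krt7 read 38.0, 10.6 and 2.17 in CTL and 49.2, 14.5 and 4.71 in Dox, and Lyz2 110, 43.1 and 18.8 in CTL and 91.4, 42.8 and 14.2 in Dox. The order of the libraries in Krt7 and Lyz2 was the same in CTL and Dox.

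Several more genes changed with doxycycline in the paired limma fit. Plod2, a collagen-modifying enzyme and a reported miR-26 target, fell by 0.65 ± 0.09 (SE, n = 3 pairs, limma adjusted p 0.015), and Prelp, a matrix proteoglycan, fell by 1.01 ± 0.22 (adjusted p 0.049, and 0.21 with DESeq2). Zbp1, a sensor of unusual nucleic acids, fell by 0.91 ± 0.18 (adjusted p 0.039). Ptch1, the receptor of hedgehog ligands, was higher by 0.68 ± 0.12 (adjusted p 0.033, and 0.070 without replicate 1). Rnf149, a ubiquitin ligase of membranes, was higher in TKO (0.67) and lower with doxycycline (-0.70), and so were Slc45a4, a membrane transporter (0.62 and -0.61), and Adcy3, an adenylyl cyclase (0.77 and -0.69). Rnf149 and Slc45a4 held the 8-base seed match, and Adcy3 held no match. Processed pseudogenes, a group picked after the values were seen, went both ways in TKO, with 50 of 141 higher and 44 lower, and 33 higher and 62 lower with the trend removed.

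Many genes differed between TKO and WT, 5796 of 12649. Removing the length and GC trend left 5785 calls, 4549 of them called both times. That count argues against the trend as the whole cause, while the trend may shape which genes pass. Calls of at least 1 log2 unit went from 344 higher and 154 lower to 177 higher and 199 lower. The balance of the larger changes thus depended on the trend. The called share among genes with no shared 50-base stretch was 0.762 of that among genes with over 0.1 shared, and thinning every library to one depth left 5741 calls, which both argue against shared reads and depth as the whole cause. The 10 splits of the 6 libraries are too few for a share under 0.05; the real split alone, 1 of 10, gave 5796 genes and the highest other gave 0. A difference other than miR-26 between the libraries, cultures or animals of the knockout and wild type stays open, untested. The labels do not say how many animals each group holds.

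Genes with a miR-26 seed match were lower with doxycycline by a median of -0.08. Of 100 heptamers with the same bases 0 gave a shift as low (lowest -0.03), which argues against base composition. Against genes matched on 3' UTR length and mean level the shift was -0.0890 (permutation p 1e-05, the smallest possible), which argues against UTR length and level. The shift is consistent with direct repression by the induced miR-26a, a hypothesis set before the data were seen, for which no independent data were tested. In TKO the shift was above 0 with the trend removed (0.04) and when set against permuted heptamers (0.0176), of which 85 of 100 gave a shift as low as the seed, so the length and GC trend may mask or mimic an effect there.

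Of the genes lower with doxycycline in the paired fit, 102 of 191 searched lacked the 7-base or 8-base seed match, and 70 of them also lacked the weaker 7-base site. Whether these 70 follow from doxycycline itself or from miR-26a cannot be told apart, since no treated culture without the transgene is among the samples. For miR-26a, an indirect route and a direct route through sites not searched stay open, untested. The search covered only the UTR of the transcript chosen for each gene, and only the matches named.

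Other splits of the libraries were too few for a share under 0.05 in every other comparison. For lists in TKO against WT 10 of 10 splits gave as many (real 1, highest other 13). For genes in Dox against CTL 10 of 10 did (real 0, highest other 0), an outcome that a real count of 0 fixes. For lists there 9 of 10 did (real 4, highest other 18). In this unpaired fit the other splits that part all 3 pairs gave 4, 4 and 3 lists. Those that part only 1 pair gave 7 to 18. Among the 4 splits that part all pairs in the paired fit, 1 of 4 gave as many genes (real 265, highest other 0) and 1 of 4 as many lists (real 10, highest other 8).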
